A study of Mus musculus with 4 samples.

How the data were processed

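Low-input ribosome profiling was done on about 1000 cells per sample, per the labels' protocols: lysates were treated with RNase I, ribosomes were pelleted through a sucrose cushion, fragments of 26 to 34 nucleotides were cut from a gel, and libraries were made with a small RNA kit that tails the fragments. No matched RNA sequencing was used here, so translation cannot be separated from transcript level. The tools named per the submitters' processing notes are Trimmomatic 0.39, STAR 2.7.5c, StringTie 2.1.7, DESeq2 and edgeR of the submitters, with the mouse build mm10; the role of each, the annotation and the counting unit are not given in the sources used here.

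The data used are 1 table of 22397 rows, with these columns per the file headers. The mean level is a signal averaged over the libraries after division by size factors, as made by the authors. The log2 fold change and its standard error are the authors' values on the log2 scale, and whether they were shrunken is not stated. The p-value and adjusted p-value of each gene are the authors' as deposited; the adjusted values differed from a Benjamini-Hochberg adjustment of the p-values by at most 6.29e-06. The table has 1 row without a gene name, with 0.00475% of the summed means, and it was left out. Of the 22396 named genes, 1882 had a mean of 0, 17347 had an adjusted p, and 3167 had reads but no adjusted p. Of these symbols 21734 matched a RefSeq gene table by symbol and 21768 by symbol or synonym; only the lengths of gene spans were used from its coordinates.

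The table has no column per sample, so the planned count test could not be the main result, and the authors' own comparison was used in its place. The sign convention of the fold changes is not stated. The mean of a gene is a sum of whole reads, each worth a fixed step per library, and solving for the steps gave 4 libraries. Of 20515 rows with reads, 20512 had 1 whole-number solution (99.985%, relative tolerance 8e-15), 3 had several and were left out (the genes mt-Cytb, Gm10800 and Gm10801), and of 500 values moved by a relative 1e-09 0 had a solution. The size factors found this way differed by at most 0.0353% from median-of-ratios factors of the recovered reads. The side of a library was read from the sign of the authors' fold change for genes whose only read lies in it, which gives the authors' grouping into sides but not which side is the knockout. No library was tied to a sample label or to a genotype. On simulated data 100% of 19984 genes were recovered exactly.

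The 37 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined, and some lists share genes; Ddx20 was left out of every list. Named genes were a fixed set of germ cell genes with Ddx20 and Thy1, the 8 genes that rose and the 8 that fell with the smallest p, a mean of at least 10 CPM and both libraries of a side beyond the other, and up to 4 members of each list with the smallest p (where none passed, the 2 with the highest mean). Predicted genes were passed over for the 8 and 8. The text leaves out part of the 156 genes this gives. Each list was tested with limma's camera on signed z values from the deposited p-values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 37 lists. Camera was also run on the recovered reads with a correlation estimated for each list. That form takes its degrees of freedom from the 4 libraries, which leave few, so it has little power. A list that misses there is not shown to be unshifted. Checked on 100 shuffles of the z values over genes, camera with the preset correlation gave 1 false call in 3700 list tests. Shuffling removes the link of direction with mean level and the correlation between genes. The check therefore does not calibrate the p-values given for the lists. The fry test of limma asks whether the genes of a list move, on balance, one way, without comparing them with other genes. It gave an adjusted p of 0.00333 for pan germ cell genes. Every other list that fry was run on was also under 0.05, except ATF4 targets (0.847), immediate early genes (0.240) and Leydig markers (0.173). As a check chosen after the data were seen, each median was set against 10000 random lists matched on mean level in 20 bins, two-sided, with Benjamini-Hochberg adjustment.

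As an added alternative, limma (voom) was run on the recovered reads of 10922 genes, with the authors' size factors, TMM, median-ratio or upper-quartile factors or library totals, with other filters (a minimum of 10 reads by default, 50 reads, or none), without the 50 most abundant genes, without mitochondrial, small RNA and predicted genes, with libraries A and B summed, and leaving out each library in turn. Tested on simulated data at these depths, with 10406 genes and an assumed dispersion of 0.05, which was not estimated from these libraries, it recovered 5.26% of 2-fold and 54.3% of 4-fold changes with 1 false call. The simulation changed 200 genes, while limma called 4045 rises and 4109 falls here. The real libraries of a side differed by about sampling noise (chi-square per degree of freedom 0.968 and 1.11). The simulated shares therefore do not give the power in these data. Agreement between libraries used a pseudocount of 1 CPM. Shares of reads have 95% Wilson intervals. Depth ranged from 221439 to 941014 reads, so genes with few reads carry wide errors. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.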

Results

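Ribosome-protected fragments were measured in mouse testis cells carrying the surface marker THY1, which were taken from Ddx20 knockout mice and from littermate controls. DDX20, also called Gemin3, is a DEAD-box RNA helicase of the SMN complex, which loads Sm proteins onto spliceosomal RNAs. The comparison addresses what loss of DDX20 does to ribosome occupancy in these cells, with prospermatogonia and the spermatogonial stem cells that arise from them as the study's subject. The labels give 2 control and 2 knockout samples, and nothing states that the samples of a group came from separate animals. The p-values therefore measure the spread between these samples. The authors' deposited table holds 1 comparison per gene, with a mean over all libraries and no column per sample. Whole reads in each of 4 libraries could be recovered from those means, and they came to 941014 reads in library A, 789570 in library B, 282722 in library C and 221439 in library D. Libraries A and B form the side of the authors' comparison with negative fold changes, and libraries C and D the side with positive ones. The table does not say which side is the knockout, so no library is given a genotype here: a gene that "rose" was higher in libraries C and D, a gene that "fell" was lower there, and all directions turn together if the sides are read the other way.

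Ddx20 itself fell, with a log2 fold change of -1.83 (standard error 0.243, Benjamini-Hochberg adjusted p = 4.07e-13) in the authors' deposited table. Its level was 305 and 309 CPM (reads scaled to a common library total) in libraries A and B, and 113 and 135 in libraries C and D, so fragments on the gene were fewer but present on the low side. Most genes of similar level fell too. In the highest of 4 equal bins by mean, which holds Ddx20 (mean 108), 2654 of 4337 genes fell, with a median of -1.05. With library totals limma gave -1.30 for Ddx20. In the authors' deposited table, 25 of 31 pan germ cell genes, 54 of 61 G1/S genes and 55 of 61 G2/M genes fell along with Ddx20, while 7 of 7 mitochondrially encoded genes and 19 of 32 interferon-stimulated genes rose. None of these 5 lists passed limma's camera with an estimated correlation (adjusted p = 0.139 with an estimated correlation for each). With 4 libraries that form of the test has few degrees of freedom and little power, so a miss there decides nothing, here and below. By the rule for named genes, those with the smallest p among the genes that fell in the authors' deposited table were Nasp, a histone chaperone (-3.33), the RNA helicase Dhx9 (-2.89), the chromatin remodeller Hells (-3.57), the germ cell RNA-binding protein Dazl (-3.61), the FACT subunit Supt16 (-2.67), the chaperonin subunit Cct8 (-2.74), the centromere protein Cenpf (-2.82) and the nuclear RNA-binding protein Hnrnpu (-2.10). By the same rule, the smallest p among those that rose in the authors' deposited table belonged to mt-Nd1 (3.16), mt-Nd5, the giant muscle protein gene Ttn (4.13), mt-Nd2 (2.96), mt-Nd4 (3.11), mt-Co1 (2.08), the histone methyltransferase gene Kmt2d (2.43) and mt-Nd6 (2.08). mt-Cytb (2.69) had a smaller p than mt-Nd2 but could not enter by this rule, as its reads were not recovered.

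In the authors' deposited table, 17347 genes carried an adjusted p, and 7920 of them passed 0.05: 4663 rose and 3257 fell, so 58.9% of the calls were rises. The direction followed the level of the gene. With the tested genes of the authors' deposited table in 4 equal bins by mean, the lowest bin held 975 rises and 0 falls, and the next 1934 and 27. In the same authors' deposited table the bin above held 1245 rises and 576 falls, and the highest bin 509 rises and 2654 falls. Of 272 genes with a mean normalized count of 200 or more in the authors' deposited table, 231 fell and 23 rose, with a median log2 fold change of -1.65. The balance of rises and falls changed with the setting. With limma on the recovered reads of 10922 genes and the authors' size factors, 4045 genes rose and 4109 fell (49.6% rises), against 5302 and 2503 (67.9%) with upper-quartile factors. Against the 4045 and 4109 of all 4 libraries, limma gave 2538 rises and 2854 falls without library C, and 2771 and 3229 without library D. The scaling moved all genes together: against the authors' size factors, library totals shifted the median log2 fold change by 0.56 and upper-quartile factors by 0.68. Genes that rose had a median of 22 reads over the 4 libraries against 289 for genes that fell, and 1394 of them had no read in library A or B.

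**Figure D1:**
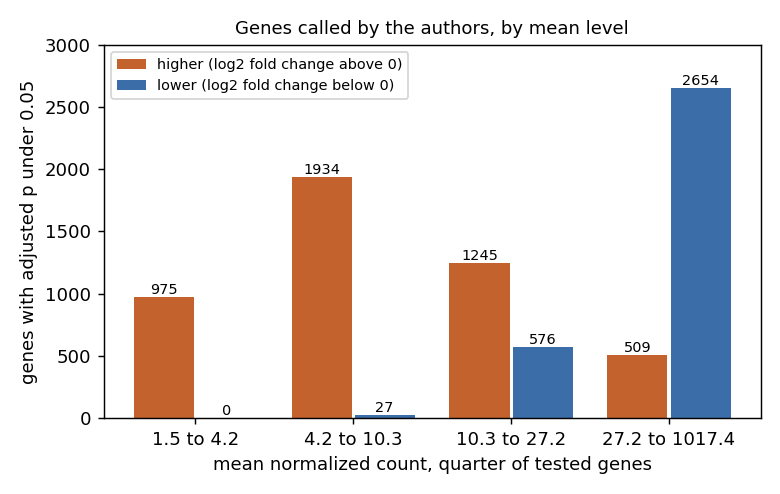
Numbers of genes with an adjusted p under 0.05 in the authors' deposited table, in 4 equal bins of mean normalized count over the tested genes; orange bars are genes that rose and blue bars genes that fell. Rises outnumber falls in the lower bins (975 and 0 in the lowest), and falls outnumber rises in the highest (2654 and 509).

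Genes that testis cells have little use for were also read in libraries C and D. Olfactory and vomeronasal receptor genes, the chemosensory receptors of the nose, took 0.806% of the reads of library C (95% Wilson interval 0.774 to 0.840) and 0.899% of library D (0.860 to 0.939), against 0.00457% of library A (0.00339 to 0.00615) and 0.00469% of library B (0.00340 to 0.00646). These intervals cover counting error only. In the authors' deposited table, 80 of 435 tested receptor genes rose and 0 fell. All 1546 receptor genes together had 43 reads in library A and 37 in library B. Receptor genes were therefore tested mostly because of reads in C and D, so a fall was hardly possible. The 0 falls say nothing about direction. The share of rises was below that of all tested genes (4663 of 17347). It was also below that of the bin of lowest means (975 of 4337, with 0 falls), so rises are not particular to receptor genes. The shares cannot be compared more closely, because reads in C and D largely chose which receptor genes were tested. Libraries C and D had reads on 19374 and 19157 genes, against 14405 and 14048 in the deeper libraries A and B. Libraries A and B differed by less than sampling noise over 8678 genes (chi-square per degree of freedom 0.968, p = 0.983), so they were also counted as 1 sample in an alternative, whereas libraries C and D differed by more than it over 7328 genes (1.11, p = 3.34e-10). Pearson's r across genes, which are not independent replicates, was 0.974 between A and B, 0.785 between C and D and 0.663 to 0.713 between the sides.

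Most tested genes on the pan germ cell list, which also holds stage markers such as Sycp3, fell, and their median was the lowest of the 37 lists. Of 31 tested pan germ cell genes in the authors' deposited table, 25 fell and 0 rose (25 and 0 adjusted over the list alone), with a median log2 fold change of -2.17. They included the RNA helicase Ddx4 (-2.97), Dazl (-3.61), the ubiquitin protease Usp26 (-4.13) and the Tudor protein Stk31 (-3.14) in the authors' deposited table. Ddx4 was at 1037 and 1047 CPM in libraries A and B and at 187 and 199 in C and D. The list lay below the other genes (limma's camera, Benjamini-Hochberg adjusted p = 1.24e-30), and its median was 1.13 log2 units under that of random lists matched on mean level (difference -1.13, permutation, adjusted p = 0.00106, the smallest these draws gave). With an estimated correlation the same list did not pass (adjusted p = 0.139 with an estimated correlation). In libraries C and D, where these genes were lower, receptor genes of the nose took 0.806% and 0.899% of reads.

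Markers of germ cell stages were tested as lists that share genes. Of their tested members, 9 of 35 undifferentiated, 13 of 24 prospermatogonia, 7 of 23 differentiating and 5 of 31 meiotic markers were also on another list, as were 14 of 31 pan germ cell genes. Among differentiating spermatogonia markers in the authors' deposited table, 13 of 23 fell and 1 rose (13 and 2 adjusted over the list alone), with a median of -1.51. Those that fell in the authors' deposited table included the RNA export factor Nxf2 (-4.05), Tex101 (-3.57), the ubiquitin hydrolase Uchl1 (-2.65), the stem cell factor receptor Kit (-1.51, also on the prospermatogonia list), the meiotic gatekeeper Stra8 (-2.13) and Sohlh1 (-1.56). Of 35 undifferentiated spermatogonia markers in the authors' deposited table, 15 fell and 3 rose (15 and 3 adjusted over the list alone), with a median of -0.86. In the authors' deposited table the stem cell transcription factors Zbtb16 (-1.58) and Etv5 (-1.79), the GDNF receptor Gfra1 (-1.67, also on the prospermatogonia list), Epcam (-3.14) and, closest to the threshold, Id4 (-0.86, Benjamini-Hochberg adjusted p = 0.0317) were among those that fell. Thy1, the marker used to isolate the cells, did not pass in the authors' deposited table (-1.05, Benjamini-Hochberg adjusted p = 0.156), with 18, 15, 1 and 3 reads in libraries A to D. Under limma on the recovered reads with the authors' size factors Thy1 passed (-1.69, adjusted p = 0.00357). It did not with upper-quartile factors (limma, adjusted p = 0.0812), library totals (0.0531), without library C (0.572) or without library D (0.234). Id4 no longer passed with limma without library B (-0.69), with library totals (-0.34) or with upper-quartile factors (-0.22). Of 24 prospermatogonia markers in the authors' deposited table, 7 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.34), including Tex19.1 (-3.26) and Morc1 (-2.67). Of 31 meiotic spermatocyte markers in the authors' deposited table, 13 fell and 4 rose (13 and 5 adjusted over the list alone; median -0.34), including the synaptonemal complex protein Sycp3 (-3.99) and the cohesins Smc1b (-3.20) and Stag3 (-2.04). In limma's camera test the Benjamini-Hochberg adjusted p was 1.19e-06 for differentiating spermatogonia, 0.00118 for undifferentiated spermatogonia, 0.0171 for prospermatogonia and 0.00644 for meiotic spermatocytes. Against lists matched on mean level only the differentiating list of these 4 passed (permutation, adjusted p = 0.00222; 0.0638, 0.749 and 0.0975 for the other 3), and none did with an estimated correlation (adjusted p = 0.139, 0.193, 0.395 and 0.290 with an estimated correlation). Leaving out library D gave an adjusted p of 0.119 for undifferentiated, 0.119 for prospermatogonia and 0.0878 for meiotic markers. Without library C the first 2 of these had 0.0697 and 0.543, and without library A prospermatogonia had 0.0618. Over the 22 meiotic markers that limma kept on the recovered reads, the median was -1.54. On all 4 recovered libraries the prospermatogonia list did not pass limma's camera with the authors' size factors (adjusted p = 0.137) or TMM factors (0.161). The prospermatogonia median turned positive with library totals (0.08) and upper-quartile factors (0.20). In the same comparison, receptor genes of the nose took 0.806% and 0.899% of the reads of libraries C and D.

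**Figure D2:**
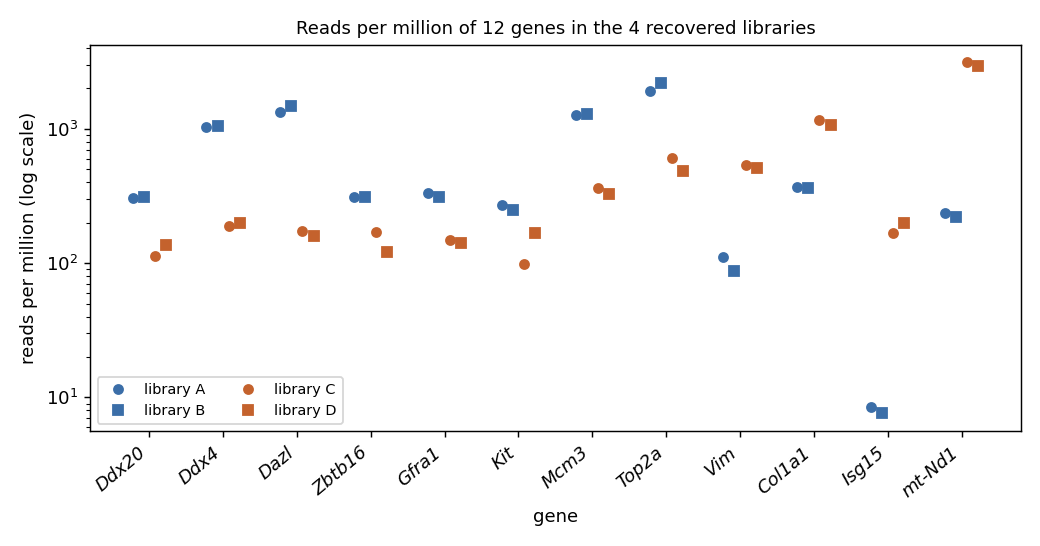
CPM on a logarithmic axis for 12 genes in each of the 4 recovered libraries; blue marks are libraries A and B, and orange marks libraries C and D. Ddx20 lies at 305 and 309 in A and B and at 113 and 135 in C and D, while mt-Nd1 lies higher in C and D.

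Most tested genes of DNA replication and mitosis fell. Pan germ cell genes fell in the same comparison (median -2.17 in the authors' deposited table), and receptor genes of the nose took 0.806% and 0.899% of the reads of libraries C and D. Of 61 G1/S and DNA replication genes in the authors' deposited table, 54 fell and 0 rose (54 and 0 adjusted over the list alone; median -1.83), among them the replicative helicase subunit Mcm3 (-2.43), the ribonucleotide reductase subunit Rrm1 (-2.55), Nasp and Hells. Of 61 G2/M and mitosis genes in the authors' deposited table, 55 fell and 0 rose (57 and 0 adjusted over the list alone; median -1.99), among them topoisomerase Top2a (-2.45), the kinesin Kif20a (-2.26), the condensin Smc4 (-2.58) and Cenpf. Of 41 cyclins, cyclin-dependent kinases and their inhibitors in the authors' deposited table, 16 fell and 4 rose (16 and 4 adjusted over the list alone; median -0.43), with Ccnd2 (-1.87), Ccnh (-3.51), Wee1 (-2.14) and Cdk1 (-1.80) among those that fell. Of 56 replication-dependent histone genes in the authors' deposited table, 31 fell and 2 rose (32 and 2 adjusted over the list alone, median -1.01), including H1f1 (-2.08) and H2bc1 (-2.89). Some genes on this list are near-identical copies, so reads may have been split between those. Another list joined the piRNA pathway, which silences transposons in germ cells, with more general silencing genes. Of its 37 genes, 27 fell and 4 rose in the authors' deposited table (28 and 4 adjusted over the list alone, median -1.65). Those that fell included Fkbp6 (-2.99), Rnf17 (-2.97) and, among the more general genes, the DNA methyltransferase Dnmt1 (-1.52). Of the 37, 19 were also on another list. Over the 37 cyclin list genes that limma kept on the recovered reads, the median was -0.79. The Benjamini-Hochberg adjusted p from limma's camera was 3.36e-34 for G1/S, 1.54e-42 for G2/M, 0.00360 for cyclins, 2.08e-06 for histones and 1.03e-19 for the piRNA and silencing list. The cyclin list had an adjusted p of 0.453 against lists matched on mean level (permutation), 0.172 without library C and 0.149 without library D. The other 4 lists passed against matched lists (permutation, adjusted p = 0.00106, 0.00106, 0.0119 and 0.00493). None of the 5 passed with an estimated correlation (adjusted p = 0.139, 0.139, 0.193, 0.324 and 0.139 with an estimated correlation).

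Most tested partners of DDX20 and genes of the splicing machinery fell as well. They did so beside the fall of pan germ cell genes (median -2.17 in the authors' deposited table) and the receptor gene shares of 0.806% and 0.899% in libraries C and D. Of the 8 other tested members of the SMN complex in the authors' deposited table, 5 fell and 0 rose (6 and 0 adjusted over the list alone; median -1.52): Gemin5 (-1.18), Gemin4 (-1.99), Gemin2 and Strap (-1.53) were among them. Gemin2 did not pass with limma without library C (adjusted p = 0.111) or without library D (0.0517). Of 20 Sm and LSm proteins and assembly factors in the authors' deposited table, 11 fell and 0 rose (11 and 0 adjusted over the list alone; median -1.23), including the arginine methyltransferase Prmt5 (-1.92), Snrpd3 (-1.94), Lsm4 (-1.83) and Lsm8 (-2.59). Over the 14 Sm list genes that limma kept on the recovered reads, the median was -1.88. Of 38 spliceosome genes in the authors' deposited table, 35 fell and 0 rose (35 and 0 adjusted over the list alone; median -1.49), including Sf3b3 (-2.20), Sf3b1 (-1.83), Snrnp200 (-1.73) and Prpf8 (-1.52). Tested as lists with limma's camera, the Benjamini-Hochberg adjusted p was 0.0123, 9.99e-05 and 7.78e-23 for the 3 lists. The spliceosome list did not pass against lists matched on mean level (difference -0.31, permutation, adjusted p = 0.157), whereas the SMN (-1.52, adjusted p = 0.00937) and Sm lists (-1.13, adjusted p = 0.00626) lay below matched lists by the same permutation. None passed with an estimated correlation (adjusted p = 0.395, 0.139 and 0.139 with an estimated correlation), and the SMN list had an adjusted p of 0.0874 without library C and 0.119 without library D.

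Genes of the translation machinery were tested as 4 lists, in the comparison in which pan germ cell genes fell (median -2.17 in the authors' deposited table) and receptor genes took 0.806% and 0.899% of the reads of libraries C and D. All 44 tested ribosome biogenesis genes fell in the authors' deposited table (44 adjusted over the list alone; median -1.73), including nucleolin (Ncl, -2.22), Heatr1 (-2.30), Utp4 (-2.58) and Nop58 (-2.53). Of 69 cytosolic ribosomal protein genes in the authors' deposited table, 18 fell and 1 rose, leaving 50 that did not pass (14 and 0 adjusted over the list alone; median -0.28), with Rpl4 (-1.23), Rps3 (-1.15), Rps9 (-1.72) and Rpl7 (-2.29) among those that fell; many of these genes have processed pseudogenes that could share reads. Over the 37 ribosomal protein genes that limma kept on the recovered reads, the median was -0.85. Of 44 initiation and elongation factors in the authors' deposited table, 30 fell and 3 rose (31 and 3 adjusted over the list alone; median -1.19), including Eif3a (-1.90), Eif3d (-2.03) and Eif5b (-2.02). Of 24 aminoacyl-tRNA synthetase genes in the authors' deposited table, 22 fell and 0 rose (24 and 0 adjusted over the list alone; median -1.53), including Dars (-2.64) and Rars (-2.21). By limma's camera the Benjamini-Hochberg adjusted p was 2.48e-33 for ribosome biogenesis, 0.0144 for ribosomal proteins, 5.83e-14 for the factors and 9.24e-18 for the synthetases. Against lists matched on mean level the first pair passed (permutation, adjusted p = 0.0102 and 0.00106) and the factors and synthetases did not (0.673 and 0.509). No list of the 4 passed with an estimated correlation (adjusted p = 0.139, 0.343, 0.139 and 0.139 with an estimated correlation), and ribosomal proteins had an adjusted p of 0.0569 without library B, 0.206 without C and 0.336 without D.

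Genes of mitochondrial proteins were tested as 1 list from the mitochondrial genome and 2 from the nuclear genome. Of the 13 protein-coding genes of mitochondrial DNA in the authors' deposited table, 7 had an adjusted p, and all 7 rose (7 adjusted over the list alone; median 2.96): mt-Nd1 went from 235 and 222 CPM in libraries A and B to 3134 and 2917 in C and D. In the same libraries C and D, the receptor genes of the nose took 0.806% and 0.899% of reads, against 0.00457% and 0.00469% in A and B. Of 76 nuclear genes of oxidative phosphorylation in the authors' deposited table, 59 fell and 0 rose (61 and 0 adjusted over the list alone; median -1.41), including Sdha (-2.26), Atp5a1 (-1.73) and Ndufv1 (-1.89). Of 76 nuclear genes for mitochondrial ribosomal proteins in the authors' deposited table, 55 fell and 0 rose (57 and 0 adjusted over the list alone; median -1.60), including Mrpl24 (-2.89), Mrps22 (-2.45) and Mrpl1 (-2.86). In limma's camera test with the preset correlation the Benjamini-Hochberg adjusted p was 1.89e-51, 4.80e-17 and 6.61e-11. The correlations estimated for these lists were higher than the preset one (0.126, 0.0599 and 0.0248), so these p-values may be too small. On the recovered reads camera with the preset correlation gave an adjusted p of 1.92e-09, 6.51e-11 and 1.75e-08. Each of the 3 lists also lay apart from lists matched on mean level (permutation, adjusted p = 0.00106 in each, with differences of 4.54, -0.77 and -1.44). With an estimated correlation none passed (adjusted p = 0.139 with an estimated correlation for each).

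Most tested genes of protein folding, protein degradation and sterol synthesis fell, again beside pan germ cell genes (median -2.17 in the authors' deposited table) and with receptor gene shares of 0.806% and 0.899% in libraries C and D. Of 48 proteasome genes in the authors' deposited table, 35 fell and 1 rose (35 and 1 adjusted over the list alone; median -1.73), including Psmd1 (-2.80) and Psma6 (-2.73). Of 35 heat shock protein and chaperonin genes in the authors' deposited table, 28 fell and 0 rose (28 and 0 adjusted over the list alone; median -1.54), including Hsp90b1 (-2.05), Hspa4 (-2.34) and Cct8. Of 24 cholesterol synthesis genes in the authors' deposited table, 13 fell and 1 rose (13 and 1 adjusted over the list alone; median -1.10), including Hmgcs1 (-2.81). Over the 18 cholesterol synthesis genes that limma kept on the recovered reads, the median was -1.72. The Benjamini-Hochberg adjusted p from limma's camera was 7.78e-23, 9.83e-30 and 2.34e-06. Heat shock genes did not pass against lists matched on mean level (permutation, adjusted p = 0.0686; 0.00185 for the proteasome and 0.0382 for cholesterol synthesis), and none of the 3 did with an estimated correlation (adjusted p = 0.139 with an estimated correlation).

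Among the lists that rose, interferon-stimulated genes had the smallest p after the mitochondrially encoded genes. Of 32 tested, 19 rose and 1 fell in the authors' deposited table (20 and 1 adjusted over the list alone; median 1.71), including the ubiquitin-like modifier Isg15 (3.83), the RNA sensor Ddx58 (3.68), Oas3 (4.37) and Bst2. Isg15 had 8 and 6 reads in libraries A and B and 47 and 44 in the shallower C and D. Of 32 markers of peritubular and interstitial stroma in the authors' deposited table, 15 rose and 3 fell (15 and 4 adjusted over the list alone; median 0.76), with vimentin (Vim, 1.81) and the collagens Col1a1 (1.04) and Col4a2 (1.42) rising and fibronectin (Fn1, -0.97) falling. Tested as lists with limma's camera, the Benjamini-Hochberg adjusted p was 4.22e-04 for interferon-stimulated genes and 0.0198 for stroma, and both passed against matched lists (permutation, adjusted p = 0.00222 and 0.00404). Neither passed with an estimated correlation (adjusted p = 0.139 and 0.187 with an estimated correlation). The receptor genes of the nose were higher in the same libraries, at 0.806% and 0.899% of reads.

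Markers of other cells in or passing through the testis mostly missed the threshold as lists in limma's camera. Of 29 Sertoli cell markers in the authors' deposited table, 3 rose and 6 fell (2 and 6 adjusted over the list alone; median -0.08), Wt1 rising (2.51) while Clu (-2.20), Ctsl (-1.15) and Dmrt1 (-1.61), a gene also expressed in spermatogonia, fell. With limma on the recovered reads the Sertoli median was 0.08 over 16 genes. Of 18 Leydig cell markers in the authors' deposited table, 2 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.37); with limma on the recovered reads the Leydig median was negative (-0.32), and positive with library totals (0.24) and upper-quartile factors (0.36). Of 20 endothelial markers in the authors' deposited table, 6 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.53), including Vwf (3.70) and Tie1 (2.58). Of 20 macrophage and myeloid markers in the authors' deposited table, 5 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.50), with Csf1r (1.70) rising and Lyz2 (-1.44) falling. Lyz2 did not pass with limma without library C (adjusted p = 0.144) or without library D (0.0554). Of 23 lymphoid markers in the authors' deposited table, 4 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.67), and the median was 2.35 over the 5 that limma kept on the recovered reads. Of 12 erythroid markers in the authors' deposited table, 8 rose and 0 fell (8 and 0 adjusted over the list alone; median 2.71), including Sptb (1.92); 4 of the 12 had no read on one side, and with those at a floor of 3 reads over a side the median was 2.58. Of 20 spermatid markers in the authors' deposited table, 9 rose and 1 fell (11 and 1 adjusted over the list alone; median 1.87, or 2.32 with the 8 genes lacking reads on one side at that floor). By limma's camera only the erythroid list of these 7 passed (Benjamini-Hochberg adjusted p = 0.0198); the others had 0.265 for Sertoli, 0.588 for Leydig, 0.186 for endothelial, 0.416 for myeloid, 0.164 for lymphoid and 0.0618 for spermatid markers. Against matched lists the Sertoli list lay lower (difference -0.72, permutation, adjusted p = 0.0113) and the erythroid list higher (1.90, adjusted p = 0.00898). By limma's fry, Sertoli markers fell on balance (adjusted p = 0.00731). Endothelial (0.00500), myeloid (0.00731) and lymphoid markers (0.0283) rose by fry, and Leydig markers did not pass (0.173). The receptor genes of the nose were higher in libraries C and D too, at 0.806% and 0.899% of reads.

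Members of the stress and growth lists rose and fell, and no such list passed limma's camera on the deposited values. In the authors' deposited table, 7 of 28 targets of ATF4, the integrated stress response factor, rose and 7 fell (7 and 7 adjusted over the list alone; median 0.24), with Cebpb rising (2.30) and Slc7a5 falling (-1.51). Of 32 p53 targets in the authors' deposited table, 5 rose and 9 fell (5 and 9 adjusted over the list alone; median -0.02), with Mdm2 (-1.60) falling. Of 30 apoptosis regulators in the authors' deposited table, 4 rose and 6 fell (2 and 5 adjusted over the list alone; median 0.14), with Diablo falling (-2.33) and Bak1 rising from 0 and 3 reads in libraries A and B to 14 and 11 in C and D. Of 21 glycolysis genes in the authors' deposited table, 3 rose and 9 fell (3 and 10 adjusted over the list alone; median -0.55), with Hk2 (-1.67) falling and Tpi1 (1.82) rising. Of 29 immediate early genes in the authors' deposited table, 7 rose and 4 fell (5 and 4 adjusted over the list alone; median 0.13), with Jund (1.43) rising and Dusp6 (-1.53) falling. None of the 5 passed limma's camera (Benjamini-Hochberg adjusted p = 0.705, 0.265, 0.505, 0.0682 and 0.902), and for the ATF4 and apoptosis lists the median and mean were above 0 while the test pointed down. For p53 targets the median and test pointed down and the mean was 0.05. By limma's fry, p53 targets (adjusted p = 0.00423), apoptosis regulators (0.00679) and glycolysis genes (0.0254) fell on balance. ATF4 targets (0.847) and immediate early genes (0.240) did not pass fry. Against lists matched on mean level, immediate early genes lay higher (difference 0.70, permutation, adjusted p = 0.0488). None of the other lists here passed that permutation (adjusted p = 0.333 to 0.900). With limma on the recovered reads and the authors' size factors the medians were 0.12 for ATF4 targets, -0.44 for p53 targets and -0.19 for apoptosis regulators. With library totals the medians of the p53 (0.11) and apoptosis lists (0.36) were positive, as they were with upper-quartile factors, where glycolysis (0.06) turned too.

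**Figure D3:**
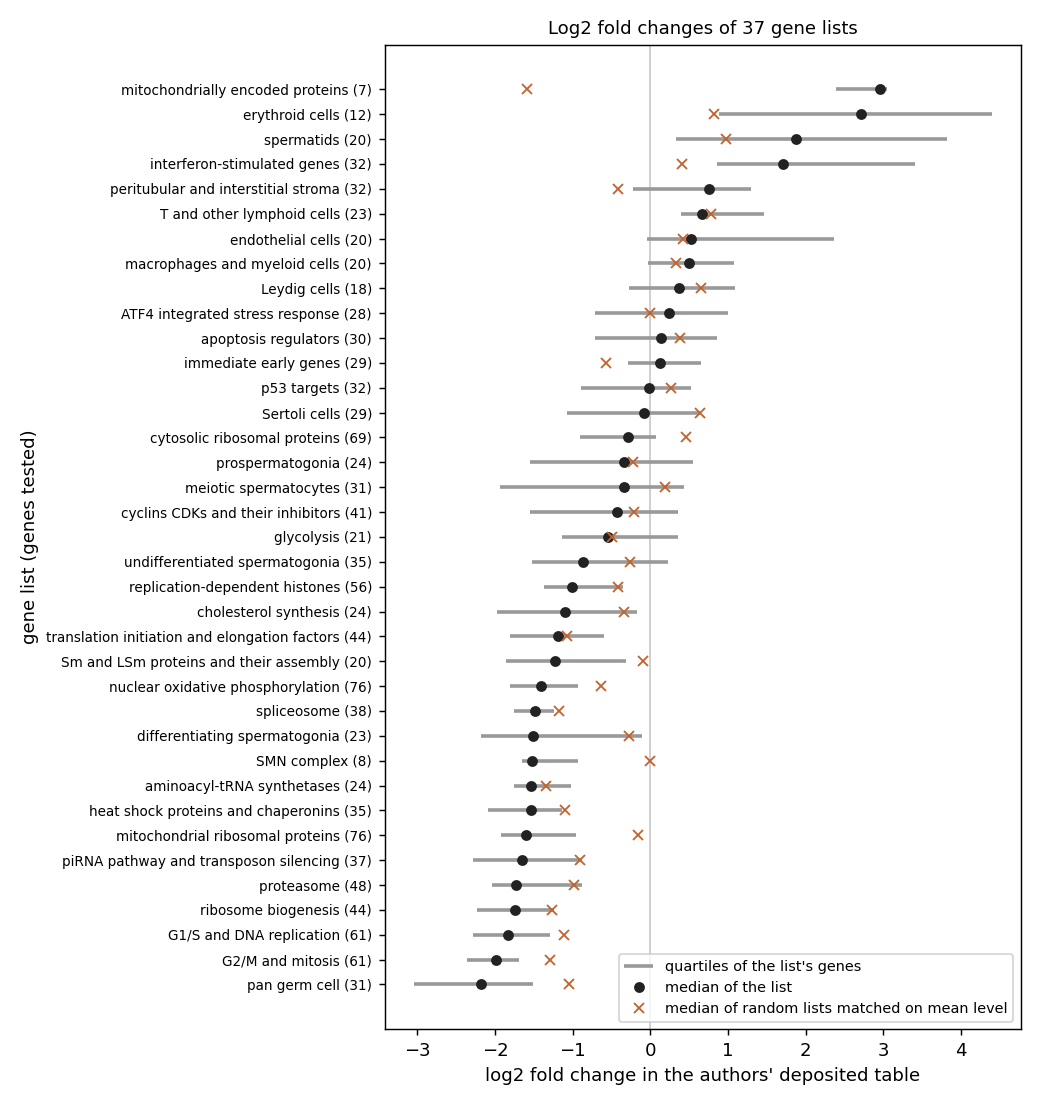
Median log2 fold change in the authors' deposited table for each of 37 gene lists (black dots), with the quartiles of its genes (grey lines) and the median of random lists matched on mean level (orange crosses); the number of tested genes follows each name. Pan germ cell genes lie lowest (median -2.17) and mitochondrially encoded genes highest (2.96), and the crosses of abundant lists such as the spliceosome lie well below 0.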

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

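Of the tests in this part, those of depth and of dilution were chosen after their results had been seen, and the share among the receptor genes that rose was added later still. The following signals lie outside the main comparison. Genes without an adjusted p took 1.24% of the reads of library C and 1.22% of library D, against 0.0711% and 0.0698% in libraries A and B. The row without a gene name had a log2 fold change of -5.21 in the authors' deposited table.

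The shallower libraries C and D had reads on more genes. Depth argues the other way: thinned to 221439 reads, libraries C and D still had 18868 and 19157 genes against 11782 and 11735, a ratio of at least 1.60 (1.601). A candidate explanation is background reads spread over genes whether or not they are expressed, since nasal receptor genes took a share 172 times as high in the lower of C and D as in the higher of A and B. No biological explanation was tested for this pattern, and because the sides of the comparison and the background coincide, background and genotype stay confounded.

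Whether background also accounts for the genes that rose stays open. Of these genes, 2.38% had a level in C and D at or below the 95th percentile of receptor genes (13.8 CPM), where background alone was taken to put most of them. That value decides nothing, because a gene must stand high in C and D to be called: among the 80 receptor genes that rose, taken here as background, the share was 17.5%. The test also takes no account of gene length. Background and a change in expression therefore cannot be told apart for these genes, and loss of DDX20, which the design names, was not tested against background.

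The lower germ cell genes may reflect fewer germ cells among the sorted cells or dilution by background. Dilution by background spread evenly over genes would lower abundant genes alike. Among genes with a mean of 200 or more, the interquartile range of log2 fold changes was 7.56 times their median error (1.22 against 0.161). That argues against even dilution as the whole cause. Background that falls unevenly on genes, for example by their length, would widen the spread as well, so uneven dilution stays open. The spermatid median (1.87) rests on few reads and is set aside: 8 of 20 genes lacked reads on one side. Lists matched to it on mean level had a median of 0.97 (permutation, adjusted p = 0.130). Fewer germ cells would lower germ cell markers by one factor, while the other germ cell list medians ran from -2.17 (pan germ cell, quartiles -3.05 to -1.51) to -0.34 (prospermatogonia and meiotic, the latter -1.54 over the 22 genes that limma kept), a spread that was not tested. It would also raise the markers of other cell types alike: the medians of Sertoli (0.04), Leydig (0.37), stromal (0.80), endothelial (0.58) and myeloid markers (0.50), without genes on a germ cell list, ranged over 0.765, and a permutation of the members gave p = 0.260 (0.2595), though against lists matched on mean level Sertoli markers lay lower (-0.72) and stroma higher (1.17), and erythroid markers, outside that test, had a median of 2.71. A change in cell composition and a change within germ cells therefore cannot be told apart here, and loss of DDX20 itself, which the design names, stays among the open explanations.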

How the results depend on the processing

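Apart from TMM, the estimated correlation, leaving out libraries, the fold thresholds and the pseudocounts, the tests here were chosen after the results were seen. The edgeR quasi-likelihood and likelihood ratio fits and the DESeq2 fit were not run. The table has no counts per sample, and on the recovered reads only limma was run. No paired analysis was possible because the recovered libraries carry no replicate number, so the replicate block was not run either. Spermatid and erythroid lists had under 5 members after limma's filter, so most settings gave no value for them. Ddx20 was lower in each of 14 alternatives (-1.97 to -1.18), and 149 of 154 named genes kept direction and call in every alternative that gave them a value. The gene mt-Cytb had none, as its reads were not recovered. Most named genes were picked for a small p in the same comparison, and the alternatives reuse its reads. The count therefore says little about how stable the calls of other genes are. Within 10922 genes limma called 3028 of the 3028 rises and 3255 of the 3255 falls of the authors' deposited table. That table held 4663 rises and 3257 falls in all. Many of its rises therefore lay outside these 10922 genes and were not tested again in that fit. The fit also used the same reads and size factors, so this overlap is not independent evidence. Where no cause is named below, the cause was not tested.

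Rises numbered 509 in the bin of highest means, 11261 with no filter, 244 with 50 reads in a side (a filter on raw reads that the deeper A and B meet more easily, which favours falls), and 2538 to 3422 leaving out a library, where fewer samples or genes enter; a lone library was assumed to vary like the other side. Across all alternatives they ranged from 244 to 11261, and falls from 2503 to 4141. Pearson's r between C and D was 0.868 with a pseudocount of 5.

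With an estimated correlation limma gave an adjusted p of 0.139 for Sm and LSm, spliceosome, translation factors, ribosome biogenesis, mitochondrial ribosomal proteins, mitochondrially encoded, oxidative phosphorylation, synthetases, G1/S, G2/M, piRNA, cholesterol, proteasome, heat shock, interferon, differentiating and pan germ cell genes. It was 0.395 for SMN and prospermatogonia, 0.343 for cytosolic ribosomal proteins, 0.910 for ATF4 (reversed), 0.193 for cyclins and undifferentiated spermatogonia, 0.324 for histones, 0.290 for meiotic genes and 0.187 for stroma. This form of the test had little power with so few libraries, so these misses decide nothing.

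With 50 reads in a side it was 0.655 for Sm and LSm, 0.999 for cytosolic ribosomal proteins, histones, undifferentiated spermatogonia, p53 and glycolysis (both reversed), 0.0631 for translation factors, 0.892 for mitochondrial ribosomal proteins, 0.238 for oxidative phosphorylation, 0.303 for cyclins, 0.345 for cholesterol, 0.722 for prospermatogonia and 0.284 for meiotic genes, while immediate early genes passed (0.00658). Camera compares a list with the other kept genes, and with 50 reads in a side the median of all kept genes was -1.37. The list medians there were -1.91 for Sm and LSm, -1.19 for cytosolic ribosomal proteins and -0.18 for immediate early genes. With no filter glycolysis (0.0101), spermatids (0.0153) and lymphoid markers (0.0448) passed, stroma did not (0.282) and immediate early genes reversed (0.357).

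Against lists matched on mean level (permutation) the adjusted p was 0.157 for the spliceosome, 0.673 for translation factors, 0.509 for synthetases, 0.453 for cyclins, 0.0686 for heat shock, 0.0638 for undifferentiated spermatogonia, 0.749 for prospermatogonia and 0.0975 for meiotic genes. Immediate early genes (0.0488) and Sertoli markers (0.0113) passed, and ATF4 (0.527), Leydig (0.387) and lymphoid markers (0.706) reversed.

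The ATF4 list reversed with the authors' factors (0.908), TMM (0.883), median-ratio (0.907), upper-quartile (0.678), totals (0.733), without the 50 most abundant genes (0.926), without mitochondrial, small RNA and predicted genes (0.875) and with A and B summed (0.871). Prospermatogonia had 0.137, 0.161, 0.137, 0.159, 0.165, 0.128 and 0.152 in the first 7 of these settings. Leaving out a library gave limma adjusted p-values of 0.0234 to 0.119 for SMN, 0.0329 to 0.336 for cytosolic ribosomal proteins, 0.0349 to 0.172 for cyclins, 0.0182 to 0.119 for undifferentiated spermatogonia, 0.0376 to 0.543 for prospermatogonia, 0.00184 to 0.0878 for meiotic genes, 0.792 to 0.925 for ATF4 and 0.532 to 0.920 for apoptosis. Across all alternatives prospermatogonia ranged from 0.00434 to 0.749, SMN from 1.27e-04 to 0.395, the pan germ cell list from 6.47e-20 to 0.139 and interferon-stimulated genes from 9.64e-05 to 0.139. Depth ran from 221439 to 941014 reads a library, and for the 1394 rises without a read in A or B the fitted fold is no bound.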

Other observations

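The genes and the measure below were all chosen after their values were seen. The median span of a gene was 30.9 kb for genes that rose, 25.1 kb for genes that fell and 22.4 kb for tested genes, a difference that was not tested. The authors' deposited table gives Gm10717, a predicted gene, a log2 fold change of 8.28, with 2, 7, 661 and 577 reads in libraries A to D. Gm11168, another predicted gene, had 1, 1, 292 and 211 reads, and Gm10720 had 0, 0, 70 and 65. Fsip2, a sperm tail gene, had 0, 0, 56 and 54 reads, Fat2, a giant cadherin, 0, 0, 44 and 36, Csmd3 0, 0, 33 and 28, and Pkhd1 0, 0, 36 and 22. Actb, the cytoplasmic actin, did not pass in the authors' deposited table (-0.10, Benjamini-Hochberg adjusted p = 0.440).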
